A study of Homo sapiens with 6 samples.

How the data were processed

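RNA was measured in 3 teratomas, which are tumours of mixed differentiated tissue that form when pluripotent cells are injected into an immunodeficient mouse. They grew for 30 days from H9, an established line of human embryonic stem cells used at passages 42 to 47. Per the labels, the cells were given to SCID-NOD mice, which lack a working adaptive immune system. The testis was the site for 2 tumours and the kidney capsule for 1. Each RNA was hybridised to 2 Affymetrix array types, U133A and U133B, which gives 6 samples. The testis tumours are numbered 1 and 2 in the order of their records, and the number pairs nothing with the kidney capsule tumour.

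The deposited values are intensities, with a single summarised signal per probe set on a linear scale. MAS5 is named in the submitters' processing notes, and its version is not given in the sources used here. On every array the mean signal after leaving out the top and bottom 2% of probe sets was between 150.02 and 150.04, as scaling of each whole array to a common target gives. The target itself is not given in the sources used here. Detection calls were not used here. No value was excluded from the deposited tables, and the 2 array types were analysed separately because they were scaled separately.

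U133A held 22283 probe sets and U133B 22645, of which 68 on each are manufacturer controls and were left out of every test. By the platform annotation, 19065 probe sets of U133A carried a single gene symbol, 1043 several and 2107 none. On U133B these counts were 15426, 554 and 6597. No gene was named from a probe set with several symbols. A probe set is a group of short probes for a transcript, and a gene may have several; the suffixes _s_at and _x_at mark those whose probes can match more than a single transcript.

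Signals were analysed as log2(signal + 32), so a fold given here is on that scale and understates the change of dim genes. Probe sets with a mean signal over the 3 tumours at or above the median of their array type were tested, 11108 on U133A and 11289 on U133B. limma 3.58.1 in R 4.3.3 was used to compare the kidney capsule tumour with the testis tumours (lmFit, then eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg threshold of 0.05). With a lone kidney capsule tumour, all spread comes from the testis pair, with 1 residual degree of freedom per probe set moderated across probe sets, and the kidney capsule tumour is assumed to vary as the testis tumours do. Beside the test, a rule of size counted probe sets at least 2-fold above or below both testis tumours. The same rule was applied with each testis tumour as the odd one out, and the testis tumours were compared with each other at 2-fold.

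Gene lists, 42 with 919 genes, were fixed before the data were examined. They cover tissues a teratoma can hold, blood and leukocytes, host kidney and testis cell types, cell cycle, apoptosis, signalling targets, mitochondria and ribosomes. Lists with at least 5 measured genes were tested with camera of limma, with its preset correlation of 0.01, on 1 probe set per gene (the one with the highest mean signal). Each list's median was also placed among 10000 random lists of the same size matched on mean signal in 20 bins. The rule for naming genes was also fixed in advance: the first 12 genes higher and 12 lower on U133A and 5 of each on U133B, ranked by the smaller of the differences from the testis tumours; up to 4 members of each list ranked the same way, or its brightest members; and 12 genes chosen for the biology of teratomas, of which POU5F1 has no probe set with a single symbol here and is not reported.

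The procedure was tested on simulated arrays with the means and spread of the real ones. For the U133A comparison with 11108 probe sets, 200 of them changed, limma called 92 of 100 probe sets changed 4-fold and 7 of 100 changed 2-fold, with 11 false calls. When the simulated kidney capsule array was given 2 times the spread of the testis arrays, false calls numbered 613. For the U133B comparison with 11289 probe sets the corresponding counts were 41, 4 and 5, and 710 with the larger spread. A list shifted by 1 on the log2 scale was called on both array types, with 0 other lists called. For the lists, neither genes that vary together nor a larger spread of the kidney capsule array was simulated. How often camera calls unshifted lists under those conditions was therefore not tested.

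The alternatives tried were other pseudocounts (1 and 100), quantile normalization, centring on the median, no filter or a filter at the 75th percentile, leaving out _x_at and _s_at probe sets, other eBayes settings, a 4-fold rule, other choices of probe sets for the lists, an estimated correlation, and leaving out each testis tumour. Raising low values to the highest Bacillus control was added after seeing the data. Bacillus controls are probe sets for bacterial transcripts and show unspecific background where no such transcript was added. The number of arrays limits the precision. Nothing in the labels says that the tumours came from separate mice or cultures, so limma p-values measure the spread between these samples only. Those of camera with its preset correlation compare a list's genes with the other genes. They do not measure spread between tumours. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.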

Results

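Expression was profiled in 3 teratomas grown for 30 days from H9 human embryonic stem cells, 2 of them in the testis and 1 at the kidney capsule of immunodeficient mice. Each tumour was hybridised to a U133A and a U133B array. Over the 11108 tested probe sets of U133A, the Pearson correlation between the testis tumours was 0.947, and the kidney capsule tumour correlated at 0.851 with testis tumour 1 and 0.798 with testis tumour 2. On U133B these values were 0.865, 0.698 and 0.617. The correlations are across probe sets, which are not independent replicates. Signals of the testis group are given as mean ± SD (n = 2), and the kidney capsule group has no replicate.

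The first comparison asked how a teratoma under the kidney capsule differed from those in the testis. Of 23 tested genes of the fibroblast and matrix list on U133A, 10 rose in the kidney capsule tumour, such as COL1A1 at 19282 against 6940 ± 2649.8 in the testis tumours (list adjusted p = 8.4e-07 by camera; adjusted p = 0.877 with an estimated correlation). Some neural genes were lower, with ZIC2 at 437.4 against 2190 ± 304.1 and DCX at 145.6 against 638.5 ± 244.1. Genes of the cell cycle were lower as a list on U133A (camera adjusted p = 1.0e-09; adjusted p = 0.877 with an estimated correlation). Embryonic haemoglobin HBZ rose from 4 ± 1.8 to 348.6. On U133A, 906 of 11108 probe sets passed limma's threshold, 403 higher and 503 lower in the kidney capsule tumour. On U133B, 505 of 11289 passed, 88 higher and 417 lower. By the rule of size, 837 probe sets of U133A lay at least 2-fold outside both testis tumours (401 higher, 436 lower), against 49 and 153 when testis tumour 1 or 2 was taken as the odd one out. On U133B the counts were 1296, 176 and 541. The limma count on U133A was 0 without the filter on low signal, with 5783 probe sets at an unadjusted p under 0.05, and that on U133B was 1 without the variance trend, with 2326. These calls assume that the kidney capsule tumour varies as the testis tumours do: in simulated U133A arrays where it varied 2 times as much, 613 of 752 calls were false. In that simulation 200 of the 11108 probe sets were changed. The share of false calls depends on that number, which is not known for the real arrays, so the share does not carry over to them. The median difference over all probe sets was 0.12 on U133A and 0.11 on U133B on the log2 scale. Centring each array on its median moved the split of limma calls on U133A to 315 higher and 1274 lower and the splits by size to 188 and 766 on U133A and 293 and 1084 on U133B, pseudocount 100 moved the limma split to 639 higher and 548 lower, and quantile normalization moved that on U133B to 472 higher and 791 lower.

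By camera, 13 of 42 gene lists passed on U133A and 2 of 29 on U133B, and 0 passed on either with an estimated correlation, where 0 had an unadjusted p under 0.05. With an estimated correlation, the correlation and the p-value of a list both rest on 1 residual degree of freedom, so hardly any list could pass. That setting therefore decides nothing about a list. With the preset correlation, camera sets a list's genes against the other genes, so a list that rose or fell did so relative to them. Its p-value does not measure spread between tumours. Between the testis tumours on U133A, the fibroblast and matrix list (-0.51) lay at percentile 0 of its matched random lists, rounded. The proliferation list (0.37) lay at percentile 100. The fibroblast and matrix list rose in the kidney capsule tumour. Its 26 genes on U133A had a median difference of 1.02 on the log2 scale (adjusted p = 8.4e-07 by camera of limma; adjusted p = 0.877 with an estimated correlation, which rests on 1 residual degree of freedom). Of 23 members past the filter, 10 rose and none fell over all probe sets tested, and 15 passed when adjusted over the list alone. COL1A1, a chain of type I collagen, rose 2.88-fold (limma adjusted p = 0.0216), and its 2 other probe sets past the filter were 1.56 and 1.60 higher on the log2 scale. COL1A2 rose 2.30-fold, COL5A2 rose 2.43-fold, and LUM, a small proteoglycan of collagen fibrils, rose 3.61-fold, from 739 ± 319.7 to 2628. ASPN, a relative of LUM, rose from 32 ± 15.7 to 322.6. On U133B the 9 measured genes had a median of 0.84 (adjusted p = 0.0273; adjusted p = 0.862 with an estimated correlation). The bone list also rose (median 0.36, adjusted p = 0.0194; adjusted p = 0.877 with an estimated correlation). The 3 of its 6 tested members that rose were COL1A1, COL1A2 and SPARC, which fibroblasts also make, and 3 passed when adjusted over the list alone. The hypoxia list did not pass (median -0.29, mean 0.03, camera adjusted p = 0.456). Of its members P4HA2, a collagen prolyl hydroxylase, rose 2.59-fold and LOX, which cross-links collagen, rose 3.28-fold, while P4HA1, also a collagen prolyl hydroxylase, read 1114 against 573.2 ± 48.3 (adjusted p = 0.0543). The testis tumours differed in the fibroblast and matrix list too, with a median 0.51 lower on the log2 scale in testis tumour 2 (-0.51), so that the kidney capsule tumour lay 0.78 above testis tumour 1 and 1.34 above testis tumour 2.

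The neural progenitor list fell on U133B (14 genes, median -0.70, adjusted p = 1.2e-04 by camera; adjusted p = 0.862 with an estimated correlation) and on U133A (17 genes, median -0.09, mean -0.36, adjusted p = 0.0456; adjusted p = 0.912 with an estimated correlation). The U133A call held under 3 of 9 alternative settings. Of 12 members tested on U133B, 5 fell, 6 when adjusted over the list alone. Of 12 on U133A, 2 fell, 4 when adjusted over the list alone. ZIC2 fell 4.71-fold, from 2190 ± 304.1 to 437.4. DLL1, a Notch ligand, fell from 485.4 ± 175 to 46.5 and OTX2, a transcription factor of forebrain and midbrain, fell 2.76-fold. The DLL1 reading of 46.5 lay below the highest Bacillus control of the kidney capsule U133B array, 152.3, so the size of its fall is uncertain. ZIC1 fell 5.19-fold, from 2873 ± 669.6 to 520.5, and its 2 other probe sets past the filter differed by -1.19 and 0.55 on the log2 scale, in opposite directions. The neuron list did not pass on U133A (30 genes, median -0.16, adjusted p = 0.0773) or on U133B (9 genes, median -0.44, adjusted p = 0.338). Among its 19 tested members 3 fell, 6 when adjusted over the list alone: the tubulin TUBB3 1.98-fold, the neurofilament NEFM 2.73-fold and DCX, a microtubule protein of migrating neurons, 3.65-fold. The neural crest and melanocyte list fell (median -0.34, adjusted p = 0.0194; adjusted p = 0.877 with an estimated correlation). The 2 of its 15 tested members that fell, 2 also when adjusted over the list alone, were the receptor KIT, from 196.3 ± 36.5 to 25.9, and MSX1 (2.57-fold), both expressed in other tissues too. On U133B the 5 measured genes of this list had a median of -1 (adjusted p = 0.0794). The second probe set of MSX1 was 0.23 higher. The KIT reading of 25.9 lay below the highest Bacillus control of the kidney capsule U133A array, 90.7. Without _x_at and _s_at probe sets the list's median was 0.17. With low values raised to the highest Bacillus control, a setting chosen after seeing the data, the calls of neural progenitor on U133A (adjusted p = 0.177) and U133B (adjusted p = 0.176) and of neural crest on U133A (adjusted p = 0.177) were lost.

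The list of cell cycle genes fell, with all 31 genes measured on U133A and a median of -0.75 (adjusted p = 1.0e-09; adjusted p = 0.877 with an estimated correlation). CDK1 fell 2.27-fold, CCNB1, its mitotic cyclin, 2.01-fold, and MCM4 of the replicative helicase 2.24-fold. These were the 3 of 31 members that passed over all probe sets, 13 passed when adjusted over the list alone, and 27 lay below both testis tumours. On U133B the 7 measured genes had a median of -0.02 (adjusted p = 0.753). The testis tumours also differed here, with a median 0.37 higher in testis tumour 2. BIRC5, which encodes survivin, an inhibitor of apoptosis needed in mitosis, read 504.3, 611.3 and 330.9 in testis tumours 1 and 2 and the kidney capsule tumour (log2 difference -0.69 ± 0.26 SE, limma adjusted p = 0.113). The list of apoptosis inhibitors had a median of -0.03 (adjusted p = 0.635) and that of apoptosis promoters -0.32 (adjusted p = 0.0988). BAK1 and BAD, both promoters, read 30.5 each against 111.8 ± 8.4 and 121.1 ± 32.5 (adjusted p = 0.064 and 0.061).

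Targets of Wnt, BMP and TGF-beta signalling fell as a list (17 genes on U133A, median -0.65, adjusted p = 0.00152; adjusted p = 0.877 with an estimated correlation). Of 13 tested, 3 fell and 1 rose, and 8 passed when adjusted over the list alone. ID3, a BMP target, fell 3.66-fold from 966.4 ± 589.9 to 216.1, while TGFBI, a matrix protein induced by TGF-beta, rose 2.35-fold from 1016 ± 78.1 to 2423. On U133B the list did not pass (6 genes, median 0.37, mean -0.10, adjusted p = 0.667), with a median of -0.05 against testis tumour 1 and 0.59 against testis tumour 2, and AXIN2, a Wnt target, fell 3.06-fold, with its 3 other probe sets past the filter also lower. The mitochondrial respiration list fell by a small amount (28 genes, median -0.24, adjusted p = 0.00595; adjusted p = 0.877 with an estimated correlation). NDUFB8 of complex I fell 2.35-fold and COX7B of complex IV 2.26-fold, the 2 of 28 that passed, with 4 when adjusted over the list alone. Its median lay at the 35.8th percentile of random lists matched on signal. Its call was lost with quantile normalization and with only genes past the filter. The Wnt, BMP and TGF-beta call was lost without _x_at and _s_at probe sets. Of the other lists that passed on U133A, neural progenitor lay at the 11.4th percentile, bone at the 93.5th and HOX 6 to 13 at the 96.5th. The rest that passed there lay at or below the 0.8th or at or above the 99th. Ribosomal proteins had a median of -0.04 and mean of 0.03 (camera direction down, adjusted p = 0.676).

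**Figure D1:**
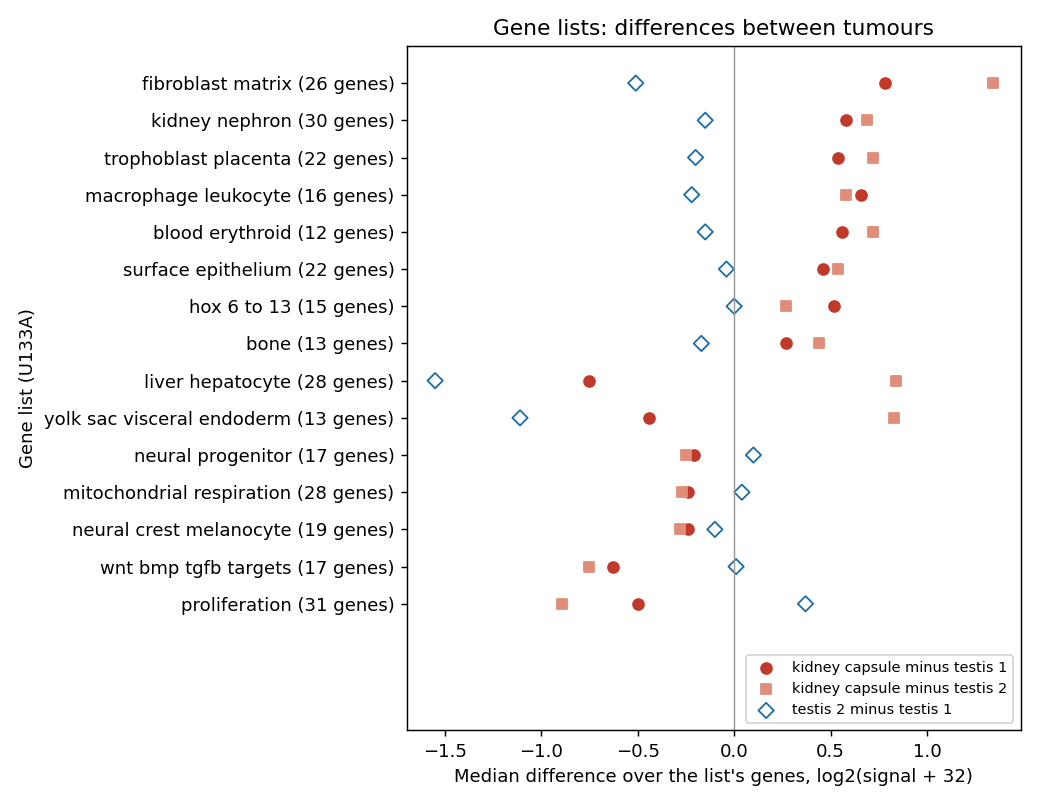
Median difference over the genes of each list on U133A, in log2(signal + 32), for the kidney capsule tumour minus testis tumour 1 (circles), minus testis tumour 2 (squares), and testis tumour 2 minus testis tumour 1 (diamonds). The 13 lists that passed camera with its preset correlation are shown with the liver and yolk sac lists, for which the kidney capsule tumour lay between the testis tumours and the diamonds sit at -1.55 and -1.11.

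Several lists of dimly expressed genes rose. The filter used the mean over all 3 tumours, so a dim gene such as HBZ (5.3, 2.8 and 348.6) could pass it through its kidney capsule signal alone. The shares of tested members that rose can therefore be raised by the filter. Erythroid genes had a median of 0.66 (12 genes, adjusted p = 0.00864; adjusted p = 0.912 with an estimated correlation), and 3 of 5 tested members rose, 4 when adjusted over the list alone. HBZ, an embryonic haemoglobin chain, rose from testis signals below the Bacillus controls, HBB, the adult beta chain, rose 2.84-fold and EPOR, the erythropoietin receptor, 2.16-fold. HBE1, the embryonic beta-like chain, read 2787, 7055 and 12916 in testis tumours 1 and 2 and the kidney capsule tumour. This probe set did not pass limma's threshold, and the other of HBE1 past the filter, 2.47 higher on the log2 scale, passed. Macrophage and leukocyte genes had a median of 0.66 (16 genes, adjusted p = 0.0167; adjusted p = 0.877 with an estimated correlation), and 2 of 5 tested members rose, 4 when adjusted over the list alone: the Fc receptor chain FCER1G 2.45-fold and CD53 2.39-fold. Kidney nephron genes had a median of 0.72 (30 genes, adjusted p = 0.00413; adjusted p = 0.877 with an estimated correlation), and 3 of 15 tested members rose, 8 when adjusted over the list alone. These were LRP2, the endocytic receptor megalin, 2.37-fold, the transcription factor PAX8 2.10-fold and the receptor RET 1.97-fold. The second probe set of PAX8 past the filter was 0.10 lower (-0.10). Trophoblast genes had a median of 0.67 (adjusted p = 0.00595; adjusted p = 0.877 with an estimated correlation), with PAPPA2 and PSG4 the 2 of 9 that rose, 3 when adjusted over the list alone. Surface epithelium had a median of 0.50 (adjusted p = 0.0121; adjusted p = 0.877 with an estimated correlation), with SFN the 1 of 6 that rose, 3 when adjusted over the list alone. HOX genes of groups 6 to 13 had a median of 0.41 (adjusted p = 0.0424; adjusted p = 0.877 with an estimated correlation), with HOXC11 the 1 of 6 that rose, 1 also when adjusted over the list alone, and the call held under 3 of 9 alternative settings. With values raised to the highest Bacillus control, the macrophage, trophoblast, surface epithelium and HOX 6 to 13 lists each had a median of 0, and of these only surface epithelium passed camera (adjusted p = 0.0224). The erythroid and nephron medians were then 0.05 each (adjusted p = 0.4 and 0.104) and that of bone 0.11 (adjusted p = 0.315), so those calls were lost too. That setting was chosen after seeing the data. It also makes many testis values equal, and camera takes its variances from them, so its p-values there decide nothing about a list. The medians do not rest on those variances.

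Array controls also differed between the tumours. Hybridisation control probe sets, for transcripts added in fixed amount to each sample in the standard protocol, read 2.19-fold higher on the kidney capsule array than on the testis arrays of U133A and 1.66-fold higher on U133B, after the authors' scaling. The highest Bacillus control read 90.7 on the kidney capsule array of U133A, against 70.6 and 55.1 on the testis arrays. On U133B it read 152.3, against 123.6 and 79.5, where the filter was at a mean signal of 97.2. Of the 403 probe sets called higher on U133A, 127 had both testis signals below 90.7. Of the 503 called lower, 265 had a kidney capsule signal below it. The ratio of the 3′ to the 5′ control signal of GAPDH, which increases as RNA degrades, was 1.33 in the kidney capsule tumour and 0.97 and 0.98 in the testis tumours.

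Ranked by the smaller of the differences from the testis tumours, the first genes on U133A besides HBZ were ATP1B1, a subunit of the sodium-potassium pump, at 6255 against 228.1 ± 102 (25.2-fold higher, limma adjusted p = 0.0055), ZBTB20, a transcriptional repressor, at 1296 against 87 ± 18.2 and CYP2E1, a liver cytochrome P450, at 582.8 against 46.4 ± 3. The other probe set of ATP1B1 was higher by 0.83 on the log2 scale, and the 5 others of ZBTB20 past the filter were all higher, by a median of 0.73. None of the 3 others of CYP2E1 was past the filter. TIMP3, an inhibitor of matrix metalloproteinases, rose 5.51-fold, and its 3 other probe sets past the filter were higher by 0.62 to 0.92. MGP, matrix Gla protein, rose 5.76-fold and CD44, a hyaluronan receptor, rose from 51.4 ± 1.6 to 339.8. The other probe set of MGP was not past the filter. With HBZ and ASPN, RNF5, GK3, SLC22A7 and H2BC6 completed the first 12 on the higher side. Of these 12, HBZ, CYP2E1, GK3, ASPN, CD44 and SLC22A7 read below the highest Bacillus controls of testis tumours 1 and 2 (70.6 and 55.1) in those tumours. The first 12 on the lower side were RUVBL2, MFN2, NUP93, RNFT2, NUP62, WNT4, MPDU1, LAS1L, MAP2K2, INSM1, STIP1 and PPP4C. Most of these are expressed in many cell types. RUVBL2, an ATPase of chromatin remodelling complexes, read 23.3 against 434.9 ± 25.7, and MFN2, a mitochondrial fusion protein, read 21 against 352.5 ± 15.1. The other probe set of MFN2 was 0.30 higher in the kidney capsule tumour, and that of INSM1 was 0.10 higher. The 2 other probe sets of NUP62, a nuclear pore protein, differed by -1.09 and 1.77. WNT4, a signalling ligand, read 10.5 against 179.2 ± 0.4 and RNFT2 read 18.1 against 261.6 ± 6.5. The other probe sets of both were also lower. Of these 12 genes, MAP2K2 alone (103.7) read above the highest Bacillus control of 90.7 in the kidney capsule tumour. Of the 414 genes called lower on U133A, 305 had other probe sets, with a median difference of -0.23 (95% bootstrap interval -0.31 to -0.16), or -0.39 past the filter, against -1.34 for the called ones. Of the 303 genes called higher, 215 had others, with a median of 0.40 (0.32 to 0.46), or 0.59 past the filter, against 1.32.

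By the same ranking the first genes on U133B were COX6A1, THBD, TEPSIN, ODAD1 and VPS53 on the higher side and SLC35B4, GOLGA2P10, ADGRV1, C1QTNF4 and ZMYND19 on the lower. COX6A1 passed limma's test at 15616 against 1296 ± 1317.6 (adjusted p = 2.3e-04), and its other probe set was 0.98 lower (-0.98). THBD, ODAD1 and VPS53 did not pass (adjusted p = 0.102, 0.165 and 0.0592). SLC35B4, a nucleotide sugar transporter, read 10.3 against 480.1 ± 11.1, with its other probe sets at -0.78 and 0.33. Every gene named here on the lower side read below the highest Bacillus control of the kidney capsule U133B array, 152.3, in that tumour. On the higher side, THBD, TEPSIN, ODAD1 and VPS53 read below those of the testis arrays (123.6 and 79.5) in testis tumours 1 and 2.

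**Figure D2:**
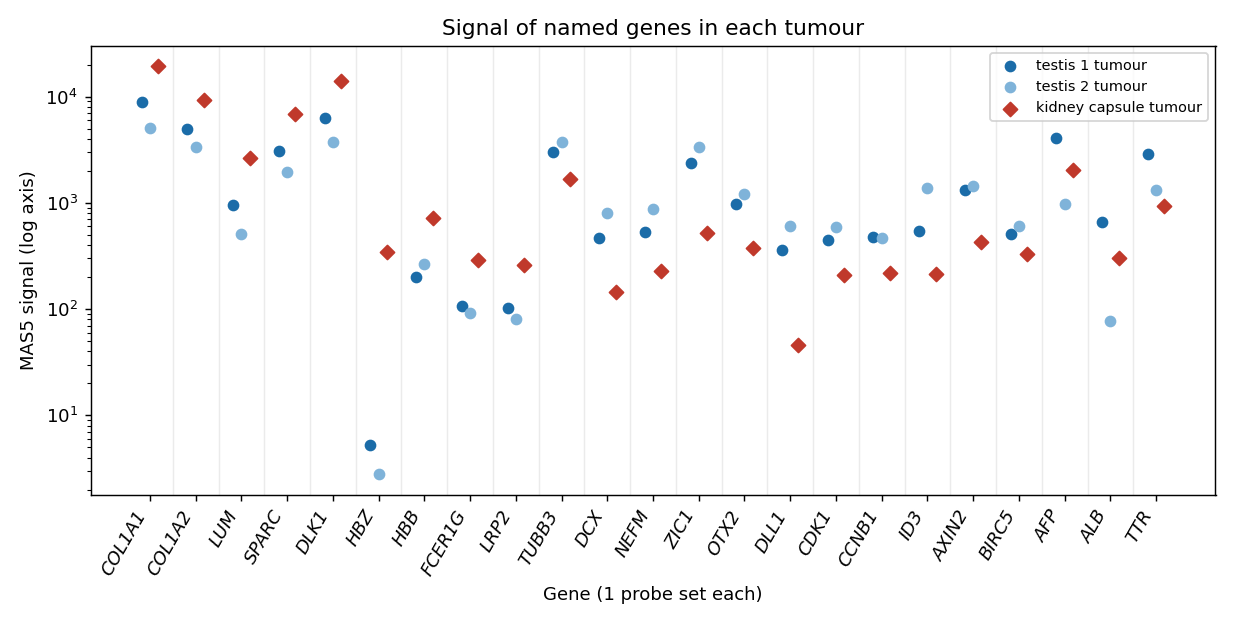
MAS5 signal on a log axis of 23 named genes in testis tumour 1, testis tumour 2 and the kidney capsule tumour, with a point per tumour and 1 probe set per gene. Collagen genes such as COL1A1 sit highest in the kidney capsule tumour (19282), neural genes such as ZIC1 lowest (520.5), and ALB separates testis tumour 1 (662.8) from testis tumour 2 (77.2).

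Pluripotency genes had a median of 0.39 on U133A (17 genes, adjusted p = 0.908) and -0.39 on U133B (11 genes, adjusted p = 0.586). Against testis tumours 1 and 2 in turn the medians were 0.21 and 0.58 on U133A and -0.14 and -0.07 on U133B. Of 7 members tested on U133B, 1 fell (LIN28B) and 1 rose (CD9, at 390 against testis signals of 104.1 and 117.3, named after its values were seen), and 5 passed when adjusted over the list alone. NANOG was dim in every tumour, at 8.4, 3.6 and 5.3. SOX2, which neural progenitors also express, read 254.7, 358.2 and 142.5 (adjusted p = 0.0691), LIN28A read 374.5, 141.4 and 143.3, and LIN28B fell 3.44-fold. DLK1, an imprinted gene, rose 2.85-fold to 13893, within an imprinted list that had a median of 0.11 (adjusted p = 0.6), or -0.12 with median centring. PAX6, COL2A1 of cartilage and AFP of fetal liver and yolk sac did not pass limma's threshold (adjusted p = 0.896, 0.321 and 0.995). KRT5 and ACTA1 lay below the filter, at 120.3 and 50.6 in the kidney capsule tumour.

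The second comparison was between the tumours grown at the same site. Liver genes separated the testis tumours: 15 of the 20 tested members of the liver list were at least 2-fold higher in testis tumour 1, and the median over 28 genes was -1.55 for testis tumour 2 minus testis tumour 1, below all of the 10000 matched random lists. ALB, serum albumin, read 662.8 in testis tumour 1, 77.2 in testis tumour 2 and 303.2 in the kidney capsule tumour. AFP read 4111, 971 and 2019, and TTR, a thyroid hormone carrier made in liver, yolk sac and choroid plexus, read 2875, 1318 and 932.5. The yolk sac list, which shares genes with it, had a median of -1.11, simple epithelium -0.64 and gut -0.44. On U133B the 7 measured liver genes had a median of -0.60. Against the testis pair, the kidney capsule tumour was intermediate, 0.75 lower than testis tumour 1 (-0.75) and 0.84 higher than testis tumour 2 in the liver list, whose median difference from the pair was 0.23 (adjusted p = 0.635). Over all tested probe sets, 239 of 11108 (2.2%) differed at least 2-fold between the testis tumours on U133A and 872 of 11289 (7.7%) on U133B. No test applies to a difference between 2 single tumours.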

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

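The tests of RNA integrity, dim signal and host kidney RNA were chosen after the results they bear on were seen, and those of other probe sets before.

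Control probe sets outside the comparisons set the kidney capsule arrays apart. The hybridisation controls were 2.19-fold brighter than on the testis arrays for U133A (log2 1.13 ± 0.16 SD over 18 probe sets) and 1.66-fold for U133B. The 3′ to 5′ ratio of GAPDH was 1.33 on U133A and 1.42 on U133B, above the testis values of 0.97 to 1.12.

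The first pattern is the set of 503 probe sets called lower in the kidney capsule tumour on U133A, where the other probe sets of the same genes had a median difference of -0.23, or -0.39 (-0.46 to -0.33) for those past the filter, of which 73% were lower. The bound set in advance for faults of single probe sets was a median above -0.25, and the first median, -0.23, meets it narrowly. Its interval, -0.31 to -0.16, which was not part of that bound, crosses it, and the second median lies between -0.25 and -0.5. Faults of single probe sets therefore cannot be told apart from a shared change of the genes. The GAPDH ratio of 1.33 lies between the highest testis value of 0.981 and the bound of 3 for degraded RNA, and integrity cannot be told apart from the site with a single kidney capsule RNA. The called probe sets were of middling brightness in the testis (median signal 278, against a median of 187 and 75th percentile of 347 for the tested ones), which leaves a loss of dim signal open as well. A biological effect of the site stays among the open explanations, untested.

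The second pattern is the set of 403 probe sets called higher, where the other probe sets of the genes had a median difference of 0.40 (0.32 to 0.46) or 0.59 (0.48 to 0.71) for those past the filter, of which 80.3% were higher. The first lies between the bounds of 0.25 and 0.5 set in advance and the interval of the second crosses 0.5, so faults of single probe sets cannot be told apart from a shared change of the genes. Of these probe sets, 31.5% had both testis signals below the kidney capsule array's highest Bacillus control, and 0% a kidney capsule signal below it. The median Bacillus control there was 18.4, against 9.8 and 9.4 on the testis arrays (on U133B 30.7, against 40.9 and 13.1). Whether brighter background on that array added to the calls was not tested. RNA of the mouse kidney next to the tumour is a candidate source: 25 measured genes of a 30-gene list abundant in mouse kidney had a median of 0.56, at the 100th percentile of matched random lists. The highest Bacillus control on the kidney capsule array was 90.7. The list was dim beside it, with a median signal of 78.4 there and 32.7 in the testis tumours. Of its 10 members past the filter 3 were called (FBP1, LRP2 and PTH1R), against 403 of 11108 probe sets, and the median was 0.68 (100th percentile) over the 14 members outside the nephron list and 0.36 (84.6th) over the 11 within it. Levels under the capsule ranged from AQP1 at 736.5 to SLC5A12 at 8.6, with SLC22A6 at 121, PCK1 at 9.5 and SLC12A1 at 11.3, genes picked after their values were seen, and kidney-like tissue formed by the human cells was not tested.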

How the results depend on the processing

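Raising low values to the highest Bacillus control was the only setting chosen after seeing the data. Counts on U133A, given in the order limma calls, 2-fold outside both testis tumours, 2-fold between the testis tumours, were 906, 837 and 239 as reported. Without the filter they were 0 (5783 at an unadjusted p under 0.05), 1528 and 540, with the filter at the 75th percentile 132, 315 and 125, and without _x_at and _s_at probe sets 271, 369 and 116. The size counts were 1391 and 496 with pseudocount 1, 293 and 97 with pseudocount 100, 60 and 27 at 4-fold, and 480 and 139 with low values raised. Limma called 1589 with median centring and 561 without the trend. With low values raised it called 943 (937 higher, 6 lower), of which 825 had equal values in the testis tumours and 158 were among the reported calls, so that count rests on spread removed by the setting. On U133B the reported counts were 505, 1296 and 872. Limma called 1263 with quantile normalization, 812 with median centring, 310 without the filter, 193 without _x_at and _s_at probe sets, 1 without the trend and 1884 with low values raised (1851 higher, 33 lower, 1743 with equal testis values). The size counts were 2320 and 2372 without the filter, 514 and 242 at the 75th percentile, 512 and 268 with pseudocount 100, 108 and 48 at 4-fold, 403 and 164 with low values raised, and 1553 for the testis pair with pseudocount 1. Leaving out each testis tumour gave 1123 to 1851 outside on U133A and 1914 to 3120 on U133B, where the rule has a single tumour to exceed. Limma has no residual degree of freedom there, and no test was run. No paired analysis was possible because nothing links a testis tumour to the kidney capsule tumour. The size counts under the filters and at 4-fold follow from the probe sets and threshold used, and for the limma counts and other settings the cause was not tested.

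Lists passing camera on U133A numbered 13 as reported, 5 without _x_at and _s_at probe sets, 6 with low values raised (5 of the reported ones) and 0 with an estimated correlation (0 at an unadjusted p under 0.05, lowest adjusted p 0.877). On U133B they numbered 2, then 1 with median centring, 1 with all probe sets of each gene, 4 with low values raised and 0 with an estimated correlation (lowest adjusted p 0.862). With low values raised, camera also takes its variances from testis values made equal by the setting, so its p-values there decide nothing about a list. The estimated correlation rests on 1 residual degree of freedom, so hardly any list could pass with it. Both settings are counted among the 9 alternatives. Of these 9, the proliferation and the fibroblast and matrix lists on U133A passed under 8. Nephron, macrophage and the Wnt, BMP and TGF-beta targets passed under 7. Erythroid, mitochondrial, surface epithelium and trophoblast passed under 6, bone under 5, neural crest under 4, and neural progenitor and HOX 6 to 13 under 3. On U133B neural progenitor passed under 7 and fibroblast and matrix under 6. Without testis tumour 1 or 2, list medians moved by more than the spread of the testis pair for 26 and 33 lists over both array types and stayed within it for 45 and 38. That spread came from each list's own median difference between the testis tumours. For a single gene the move can never exceed it, so these counts arise from how medians combine within a list. They do not measure how stable a list is. Lists whose median had opposite signs against testis tumours 1 and 2 were, on U133A, HOX 1 to 5 (0.37 and -0.56), liver (-0.75 and 0.84), retina (-0.19 and 0.23), ribosomal (0.04 and -0.12) and yolk sac (-0.44 and 0.83). On U133B they were apoptosis promoters (-0.24 and 0.13), cartilage (-0.08 and 0.78), endothelium (-0.40 and 0.37), proliferation (-0.26 and 0.20) and the Wnt, BMP and TGF-beta targets (-0.05 and 0.59). None of these had passed. Of the reported lists that passed, the median of only neural crest changed sign, to 0.17 without _x_at and _s_at probe sets.

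These U133A medians, of lists that did not pass, also changed sign. Without _x_at and _s_at probe sets apoptosis inhibitors were at 0.13, apoptosis promoters at 0.03 and choroid plexus at -0.30. With median centring glia was at -0.11, imprinted -0.12, pancreas -0.02, retina -0.22, germ cell -0.11 and yolk sac -0.13. With quantile normalization apoptosis inhibitors were at 0.04 and retina at -0.17. With all probe sets of each gene apoptosis inhibitors were at 0.18, HOX 1 to 5 at 0.08, hypoxia 0.17, neuron 0.05 and retina -0.02. With only genes past the filter apoptosis inhibitors were at 0.18, steroidogenic and Sertoli genes at -0.06, pluripotency -0.02 and retina -0.02. AFP was at 0 with pseudocount 100 and -0.22 with median centring, and PAX6 at -0.14 with median centring. On U133B, endothelium was at -0.11 with quantile normalization and -0.13 with median centring, and proliferation at 0.01 with pseudocount 1. Mitochondrial respiration was at 0.07 without _x_at and _s_at probe sets and 0.16 with all probe sets, where trophoblast was at -0.14 and Wnt, BMP and TGF-beta targets at -0.30. The cause of these was not tested.

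Of 82 named genes that passed, the calls of 12 remained without the filter, 46 without the trend, 70 with pseudocount 1, 73 with median centring, 75 with quantile normalization, 77 with robust eBayes, 82 with pseudocount 100 and 18 with low values raised. Signal over background limits the lower values: of the 503 probe sets called lower on U133A, 265 read below the highest Bacillus control of 90.7 in the kidney capsule tumour.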

Other observations

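The tests of the liver pattern were chosen after it was seen, and those of the difference between sites before.

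Other tissue lists, which did not pass camera on U133A, had these medians in the kidney capsule tumour minus the testis tumours: cartilage 0.51, smooth muscle 0.49, adipocyte 0.47, intestine 0.41, skeletal muscle 0.34, ciliated airway 0.34, endothelium 0.34, cardiac muscle 0.27, basement membrane 0.25, choroid plexus 0.23, simple epithelium 0.33, yolk sac 0.10 and pancreas 0.21. With median centring, pancreas (-0.02) and yolk sac (-0.13) lay below 0. CD36, a fatty acid transporter of adipocytes, endothelium and macrophages, rose from 42.5 ± 16.6 to 260.7, and CILP, a cartilage matrix protein, rose 2.58-fold. None of the 4 other probe sets of CD36 was past the filter. Definitive endoderm had a median of 0.64 on U133A and 0.55 on U133B, and passed on both with low values raised to the highest Bacillus control (medians 0.25 and 0.01, adjusted p = 0.0153 and 0.0188), a setting chosen after seeing the data. Camera takes its variances there from testis values made equal by the setting, so passing decides nothing about definitive endoderm. Interferon response had a median of 0.33, immediate early genes 0.34 and HOX genes of groups 1 to 5 -0.13. The median and the direction of camera differed for glia (0.12) and retina (0.01), both downward by camera, and on U133B for endothelium (0.07) and the Wnt, BMP and TGF-beta targets (0.37). Camera sets the genes of a list against the other genes, so its direction need not be the sign of the median. For apoptosis promoters on U133B the median was -0.12 and the mean 0.05. With median centring the glia median was -0.11 and that of retina -0.22. In the retina list the chaperone CRYAB rose 3.11-fold and the retinoid carrier RLBP1 from 59 ± 22.4 to 239.3.

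Lists of host testis cell types did not pass with the reported settings. The p-value given below with low values raised decides nothing, for the reason given for definitive endoderm. Steroidogenic and Sertoli cell genes had a median of 0.45 and germ cell genes 0.12, with adjusted p = 0.113 and 0.743 by camera, and the germ cell median was -0.11 with median centring. On U133B the 5 measured steroidogenic and Sertoli genes had a median of 1.24 (adjusted p = 0.144, or 0.0424 with low values raised to the highest Bacillus control, a setting chosen after seeing the data).

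The third pattern is the lower level of liver genes in testis tumour 2. Independent scatter of single genes is argued against, since 100% of the 10000 matched random lists had a smaller absolute median difference between the testis tumours, and in 0 of 10000 draws of all 42 lists did any lie as far (at most 0.74). This is not particular to liver, since 6 lists lay at percentile 0 and 3 at percentile 100 of their own random lists, rounded. A fault of the single U133A array cannot be told apart from a change in the RNA: the median on U133B was -0.60, but its interval over 7 genes was -1.49 to 0.03, and other lists were about as low there, such as cartilage at -0.67 and endothelium at -0.58. The design puts these tumours in the same group, so no biological explanation was tested.

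Ordinary variation and array noise were also tested as sources of the difference between sites. The kidney capsule tumour had 837 probe sets of U133A at least 2-fold outside both others, against 153 for the more distant testis tumour, which exceeds the bound set in advance. That bound was too lenient: among 3 tumours any could be the most distant without an effect of site, so ordinary variation between tumours cannot be told apart from the site. Noise of single arrays is argued against for the 100 probe sets printed on both array types, whose differences correlated at 0.882 across probe sets (95% interval 0.829 to 0.919). Of these, 73 had the same sign on both, the mean disagreement was 0.29, and the same RNA was used on both. Their differences had an SD of 0.41 on U133A. Noise of other probe sets, such as those called with signals below the Bacillus controls, was not tested.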
